A study of Mus musculus with 123 samples.

How the data were processed

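Whole lung RNA of 123 BALB/c mice was measured, with 1 array per mouse, in 16 groups of 6 to 8 mice. The groups combine 2 arms, naive and sensitized to ovalbumin (OVA), with 8 times from 0 to 168 h after the OVA challenge. Each array carries its own animal number in the labels, so the replicates are separate animals and the spread between them is biological as well as technical. Replicate numbers follow the order of the deposited samples and pair nothing across groups.

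Total RNA was amplified and labelled with biotin by a 3′ in vitro transcription kit from Affymetrix, per the labels' protocols, which also state that the RNA integrity number was above 6 in all samples. The deposited values are log2 values, with 1 for each probe set and array, made with RMA per the submitters' processing notes. RMA as usually run corrects the background, normalizes arrays by quantiles and summarizes the probes of a set on the log2 scale, which removes differences in total signal between arrays and compresses low signals. Its version and the filter that selected the probe sets are not given in the sources used here. The table holds 25697 probe sets, 10 of them controls, and the lowest of the probe sets' highest values was 7.03. Array medians lay between 9.32 and 9.44 and upper quartiles between 10.79 and 10.89, and no further normalization was applied. Arrays give no counting depth, and the number of arrays limits the precision.

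Probe sets were named through the platform annotation supplied with the values. Of them, 22478 probe sets had 1 gene symbol, 259 had several and were not named, and 2950 were not listed with a gene. Control probe sets were left out of the gene tests. The 3′ and 5′ control probe sets of actin gave a measure of RNA quality per array, their log2 difference, which was compared between the arms at each time by a two-sided exact permutation test adjusted over the 8 times. For a gene with more than 1 probe set (5672 genes), the probe set with the highest mean over all arrays was used, which left 13053 genes. No pair of arrays held identical values, and the highest correlation between a pair of arrays over these genes was 0.9973.

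A linear model with 1 mean per group was fitted to all 123 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with version 1.17.8 of data.table, leaving 107 residual degrees of freedom. All groups share 1 estimate of the spread per gene. Where the mice compared vary more than the other groups, the SE and p of the model understate their spread. The sensitized minus naive difference was tested at each time, the change of that difference since 0 h was tested at each later time, and moderated F tests over the 7 differences from 0 h were made in naive mice, in sensitized mice and for the sensitization by time interaction. P-values were adjusted within each contrast by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p given for a single gene comes from limma. Differences are on the log2 scale, sensitized minus naive, with the standard error (SE) of the model, so a difference of 1 is a 2-fold change of the deposited signal.

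Before the data were examined, 39 gene lists of immune and lung cell types, pathways and neighbouring tissues were fixed. The mean log2 value over the measured members of a list was computed per mouse and compared between the arms at each time by a two-sided exact permutation test. The 312 p-values were adjusted together. With 8 mice against 8 the smallest p these tests can give is 0.00016 before adjustment. Members past the threshold were counted over all genes and adjusted over the list alone. Camera of limma, which compares a list with all other genes, was run with an estimated inter-gene correlation. Changes of a list over time in naive mice were tested by permutation with 100000 resamples, whose smallest p is 1e-05, adjusted over the 39 lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the list tests and figures. A further list of squamous epithelium genes was chosen after the data were seen.

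Named genes follow a rule fixed before the data were examined. At each time it takes the 8 genes with the highest and the 5 with the lowest difference past the threshold. For each list it takes up to 4 members with the largest absolute difference at the time when the list differed most. It also takes the 10 genes with the largest range of time means in naive mice and the 10 with the largest range of interaction contrasts, and a panel of 17 genes of allergic inflammation. 14 panel genes were among the genes tested, and Arg1, Retnla and Mki67 were not analysed here. Any other member of a fixed list could be named beside its list's count.

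The model step was tested on simulated data for the 13053 genes, drawn as independent normal noise with the same SD of a gene in all groups. Real genes are correlated and the spread differs between groups, so these shares do not give the error rate of the real data. For the comparison at 6 h it called 86% of genes made different by 1.5-fold, 94% at 2-fold and 98% at 4-fold, with 8 unchanged genes called. For 24 h these shares were 88%, 94% and 100%, with 13 unchanged genes called. For the change from 0 h to 6 h they were 82%, 90% and 98%, with 12 unchanged genes called. In the simulated naive time course 92% of the genes made to differ by 2-fold were called, with 2 unchanged genes. In simulated contrasts at 0 and 48 h, where nothing was changed, 0 genes were called. The exact permutation test of a list score gave p under 0.05 in 7% of simulations without a shift, 42.3% with a shift of 1 SD and 98.3% with 2 SD at 8 mice against 8.

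Alternatives were set before the data were examined: testing every probe set, averaging the probe sets of a gene, leaving out the 40% of genes with the lowest mean, centring each array on its median, repeating the quantile normalization, a trended and robust variance model, array weights, fitting only the groups compared, and, for lists, the median over members, per-gene z scores and camera. Leaving out single mice, and leaving out the arrays with high squamous epithelium or skeletal muscle scores (a mean above 8), were added after seeing the data, as were the actin 3′ minus 5′ value as a covariate, the naive lists among 24 to 96 h alone and all settings but the 40% filter for the changes since 0 h. The labels give no array batch or date. No sample was left out of the reported comparisons.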

Results

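Gene expression was measured in whole lungs of BALB/c mice in a model of allergic asthma, in which mice are sensitized to the egg protein ovalbumin (OVA) and later challenged with it. The 61 naive mice were sampled in groups of 8 at 0, 6, 24, 72 and 168 h after the challenge and of 7 at 2, 48 and 96 h. The 62 sensitized mice were sampled in groups of 8 at each of these times except 24 h, which had 6. The design text gives 8 animals per time. It says that both arms were challenged with OVA, while the titles of the naive samples carry the word PBS, so what the naive mice received stays open. Whether 0 h lies before the challenge or just after one is not given in the sources used here, so what the change since 0 h is measured from stays open too. The comparison of the arms asks how sensitized and naive lungs differ at each time. If the naive mice received PBS, it mixes sensitization with the challenge itself. Array medians spanned 9.32 to 9.44 on the log2 scale. Some arrays carried transcripts of neighbouring tissue: the mean of squamous epithelium genes was at least 9.25 in 7 arrays and at most 6.04 in the others, and 3 further arrays had high skeletal muscle scores.

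At 0 h the lungs of sensitized mice differed from naive lungs, among others in genes of mucus-producing cells. Clca1, a secreted goblet cell protein, stood at 14.08 ± 0.14 (SD, n = 8) in sensitized and 5.71 ± 0.70 (SD, n = 8) in naive lungs. Chil4, a chitinase-like protein induced by IL-4 and IL-13, was higher by 5.82 ± 0.66 (SE), and the anion exchanger Slc26a4 by 4.62 ± 0.47. Chil4 did not separate all mice: naive replicate 1 stood at 12.24, above sensitized replicates 7 and 8 at 11.89 and 12.22. The other naive mice stood between 5.70 and 7.99. The actin-severing protein Scin was higher by 4.09 ± 0.36, the mucin glycosyltransferase Gcnt3 by 4.08 ± 0.29, Capn9 by 3.84 ± 0.33, AA467197 by 3.48 ± 0.44 and the gel-forming mucin Muc5ac by 3.46 ± 0.31. All 16 measured goblet cell and mucus genes rose, and 16 rose adjusted over the list alone. Their mean was higher by 2.84 (adjusted p = 0.00099, exact permutation test), with 8 of 8 sensitized mice above every naive mouse. It also passed against all other genes (adjusted p = 0.00332 with an estimated correlation). All 22 measured cell cycle genes rose, 22 adjusted over the list alone, such as Hmmr by 1.08 ± 0.24 and Cdca8 by 1.16 ± 0.20. The cell cycle mean was higher by 0.75 (adjusted p = 0.00117, exact permutation test), above every naive mouse in 7 of 8 (adjusted p = 0.193 with an estimated correlation).

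Of the 9 measured CC chemokines of allergic inflammation, 7 rose at 0 h and none fell (8 adjusted over the list alone). The monocyte and eosinophil attractant Ccl8 rose by 3.29 ± 0.37 and eotaxin, Ccl11, by 1.53 ± 0.36. The CC chemokine mean was higher by 1.35, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.199 with an estimated correlation). Of the 10 measured IL-4 and IL-13 responsive macrophage genes 8 rose (8 adjusted over the list alone). The responsive macrophage mean was higher by 1.5, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.123 with an estimated correlation). Of 11 type 2 cytokines and receptors 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a mean higher by 0.51, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.492 with an estimated correlation). Il13 rose by 1.36 ± 0.32, while Il4 differed by 0.38 ± 0.37 and was not called (adjusted p = 0.462). Of 13 plasma cell genes 6 rose and 1 fell (8 and 1 adjusted over the list alone), among them the immunoglobulin heavy chain Ighm by 2.65 ± 0.50. The plasma cell mean was higher by 0.60, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.317 with an estimated correlation).

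The lowest genes at 0 h were the adipocyte hormone Adipoq at -3.04 ± 0.79, the muscle actin Acta1 at -2.71 ± 0.73, Car3 at -2.43 ± 0.69, Tmem45b at -2.40 ± 0.63 and Pck1 at -2.17 ± 0.59. Of 8 adipocyte markers 3 fell (6 fell and 1 rose adjusted over the list alone). The adipocyte mean was -1.10 (adjusted p = 0.00099, exact permutation test), below every naive mouse in 8 of 8 (adjusted p = 0.463 with an estimated correlation). Of 9 skeletal muscle markers 3 fell (6 adjusted over the list alone), with a mean of -1.46, below every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.503 with an estimated correlation). Of 10 cardiac muscle markers 1 fell, and 1 adjusted over the list alone, with a mean of -0.93, below every naive mouse in 6 of 8 mice (adjusted p = 0.0112, exact permutation test; adjusted p = 0.608 with an estimated correlation). Naive replicates 1 and 3 at 0 h had high squamous epithelium scores, 12.17 and 13.21. Without the arrays of that kind the skeletal muscle difference was -0.33 and the adipocyte difference -1.10. In limma 3457 of 13053 genes passed the threshold at 0 h, 1850 higher and 1607 lower. The count was 2003 without sensitized replicate 6 and 2044 without sensitized replicate 1.

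**Figure D1:**
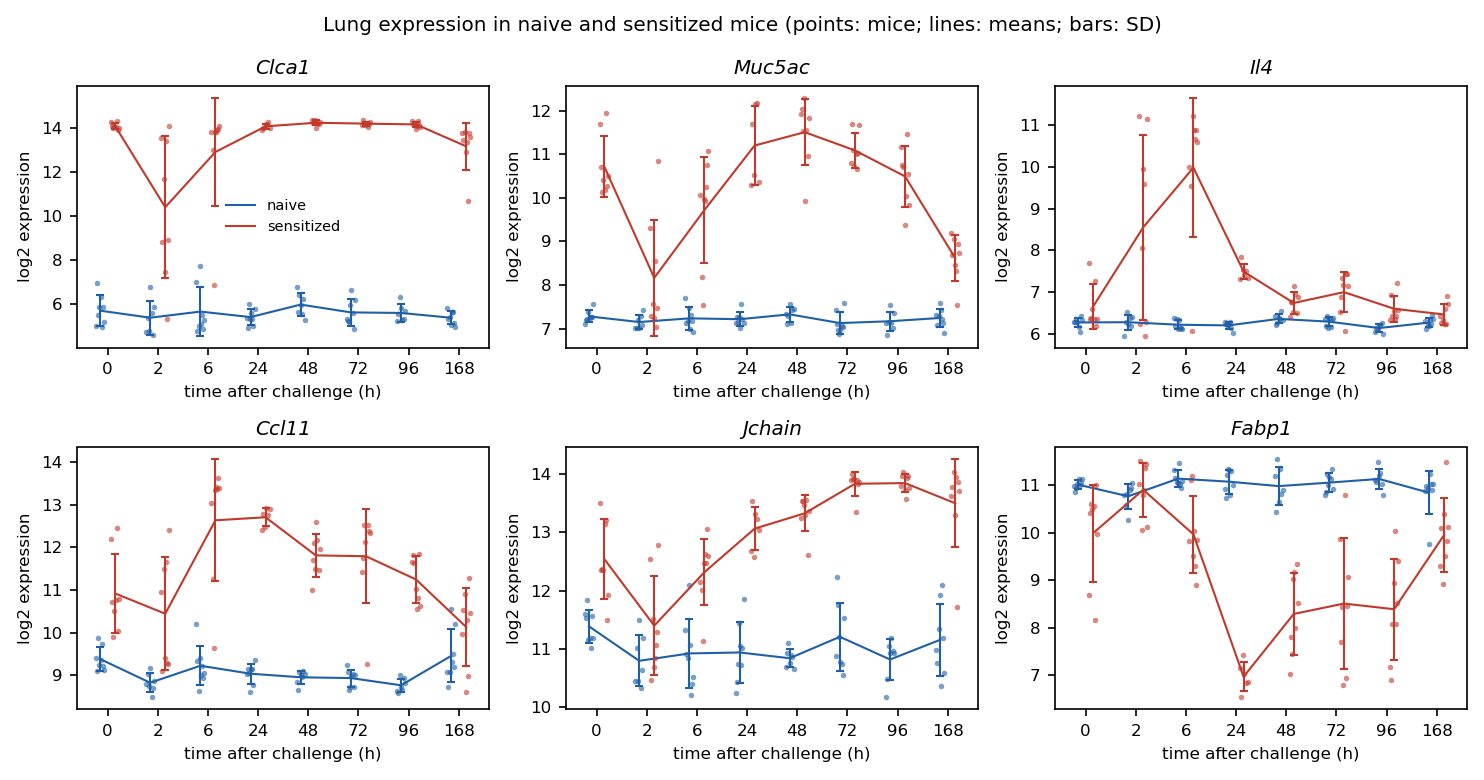
Log2 expression (y axis) of Clca1, Muc5ac, Il4, Ccl11, Jchain and Fabp1 in each naive (blue) and sensitized (red) mouse against the time after challenge in h (x axis, evenly spaced categories); lines join group means and bars are SD. Clca1 stood at 14.08 in sensitized mice at 0 h and had an SD of 3.23 at 2 h, while Il4 was highest at 6 h.

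At 2 h fewer genes differed, and the sensitized mice varied widely among themselves. Clca1 was higher by 5.01 ± 0.60 (SE, 8 sensitized and 7 naive mice), with an SD of 3.23 between sensitized and 0.77 between naive mice. This SE comes from the spread shared by all groups and understates that of these sensitized mice. The neutrophil attractant Cxcl3 was higher by 2.40 ± 0.55, the acute phase cytokine Il6 by 2.30 ± 0.58 and the type 2 cytokine Il4 by 2.27 ± 0.38. Chil4 was higher by 2.19 ± 0.68, Slc26a4 by 2.05 ± 0.49, Ighm by 1.99 ± 0.52 and the itaconate-producing enzyme Acod1 by 1.97 ± 0.47. Of 24 acute inflammatory cytokines and acute phase genes 14 rose and none fell (20 adjusted over the list alone). The acute inflammatory mean was higher by 0.96 (adjusted p = 0.0169, exact permutation test), above every naive mouse in 6 of 8 mice, and passed against all other genes (adjusted p = 0.0274 with an estimated correlation). Of 12 neutrophil markers 4 rose (8 adjusted over the list alone), namely the pattern receptor Clec4e by 1.41 ± 0.30, the collagenase Mmp8 by 1.28 ± 0.35, Il1r2 by 0.99 ± 0.29 and the chemokine receptor Cxcr2 by 0.98 ± 0.30. The neutrophil mean was higher by 0.68, above every naive mouse in 8 of 8 (adjusted p = 0.00117, exact permutation test; adjusted p = 0.18 with an estimated correlation). Of 13 glucocorticoid-responsive genes 6 rose (6 adjusted over the list alone), among them Zbtb16 by 1.40 ± 0.38, the chaperone Fkbp5 by 1.35 ± 0.19 and the metallothionein Mt2 by 1.08 ± 0.24. The glucocorticoid-responsive mean was higher by 0.37, above every naive mouse in 7 of 8 mice. Its adjusted p was 0.00473 in the exact permutation test and 0.214 with an estimated correlation. In naive mice this mean was 12.11 at 0 h, 11.81 at 2 h and 12.17 at 6 h. The naive neutrophil mean was 9.705 at 0 h, 9.22 at 2 h and 9.876 ± 1.22 (SD) at 6 h. Both differences at 2 h thus rest partly on naive means lower than at 0 and 6 h.

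Of 16 goblet cell and mucus genes 3 rose at 2 h (9 adjusted over the list alone), while Muc5ac at 1.02 ± 0.32 and Gcnt3 at 0.54 ± 0.30 were not called. The goblet cell mean was higher by 1.01 (adjusted p = 0.0313, exact permutation test), above every naive mouse in 5 of 8 (adjusted p = 0.143 with an estimated correlation). Of 13 alveolar macrophage markers 1 rose (8 adjusted over the list alone). The alveolar macrophage mean was higher by 0.30, above every naive mouse in 6 of 8 mice (adjusted p = 0.00306, exact permutation test), and it passed against all other genes (adjusted p = 0.0208 with an estimated correlation). Of 8 B cell markers 2 fell (6 adjusted over the list alone), with a mean of -0.50, below every naive mouse in 6 of 8 (adjusted p = 0.0263, exact permutation test; adjusted p = 0.277 with an estimated correlation). In naive mice the alveolar macrophage mean was 10.19 at 0 h, 9.979 at 2 h and 10.21 at 6 h. The naive B cell mean was 9.867, 10.29 and 9.97 at these times. Both differences at 2 h thus rest partly on naive means that departed from those at 0 and 6 h. Tnfrsf13c, the receptor for the B cell survival factor BAFF, stood at -0.91 ± 0.19. The other lowest genes were Klhl14 at -1.28 ± 0.20, 4930426D05Rik at -1.21 ± 0.23, Ppp2r2c at -0.96 ± 0.28 and Srpk3 at -0.93 ± 0.19. In limma 491 genes passed the threshold, 240 higher and 251 lower. The count was 197 without sensitized replicate 8, 289 without sensitized replicate 5, 308 without naive replicate 6 and 324 without sensitized replicate 3, naive replicate 3 or naive replicate 4. It was 1379 with array weights.

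At 6 h genes of mucus, chemokines and cytokines were higher in sensitized mice. The interferon-inducible chemokines Cxcl11 and Cxcl9 were higher by 5.57 ± 0.48 and 5.13 ± 0.50 (SE; 8 and 8 mice), the dendritic cell lectin Cd209e by 4.95 ± 0.44 and the neutrophil attractant Cxcl5 by 4.83 ± 0.56. The retinoic acid-producing enzyme Aldh1a3 was higher by 4.74 ± 0.41, although 2 other probe sets of Aldh1a3 differed by 0.35 and 2.04. Clca1 was higher by 7.24 ± 0.58, Chil4 by 4.89 ± 0.66 and Slc26a4 by 4.81 ± 0.47. All 16 goblet cell and mucus genes rose, 16 adjusted over the list alone, with a mean higher by 2.52, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.123 with an estimated correlation). Il4 stood at 9.98 ± 1.67 (SD, n = 8) in sensitized and 6.22 ± 0.11 (SD, n = 8) in naive mice (adjusted p = 3.63e-15, limma). This p rests on the spread shared by all groups, which understates that of the sensitized mice here. Sensitized replicate 3 stood at 6.07. Il13 was higher by 3.09 ± 0.32, Il5 by 2.81 ± 0.29 and Il10 by 2.62 ± 0.29. Of 11 type 2 cytokines and receptors 9 rose and 1 fell, and the same numbers adjusted over the list alone. Their mean was higher by 1.75 (adjusted p = 0.00238, exact permutation test), above every naive mouse in 7 of 8 (adjusted p = 0.122 with an estimated correlation).

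All 9 CC chemokines of allergic inflammation rose at 6 h, 9 adjusted over the list alone. The T cell attractants Ccl22 and Ccl17 rose by 3.60 ± 0.30 and 3.31 ± 0.32, and the eotaxins Ccl11 and Ccl24 by 3.40 ± 0.36 and 3.23 ± 0.34. The CC chemokine mean was higher by 2.68, above every naive mouse in 7 of 8 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.123 with an estimated correlation). Of 24 acute inflammatory genes 22 rose (23 adjusted over the list alone), including Cxcl3 by 4.60 ± 0.54, Il6 by 4.29 ± 0.56 and the protease inhibitor Timp1 by 3.14 ± 0.33. The acute inflammatory mean was higher by 1.84, above every naive mouse in 7 of 8 (adjusted p = 0.00383, exact permutation test; adjusted p = 0.123 with an estimated correlation). All 23 interferon-stimulated genes rose, 23 adjusted over the list alone, with Cxcl10 at 4.37 ± 0.43, the nucleic acid sensor Zbp1 at 2.25 ± 0.23 and the GTPase Iigp1 at 2.24 ± 0.23. The interferon-stimulated mean was higher by 1.38, above every naive mouse in 7 of 8 mice (adjusted p = 0.00238, exact permutation test; adjusted p = 0.143 with an estimated correlation).

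Of 17 T cell markers 16 rose at 6 h (17 adjusted over the list alone), led by the activation markers Il2ra at 2.78 ± 0.24 and Ctla4 at 2.11 ± 0.23. The T cell mean was higher by 0.98, above every naive mouse in 7 of 8 mice (adjusted p = 0.00306, exact permutation test; adjusted p = 0.209 with an estimated correlation). Of 13 dendritic cell markers 11 rose (11 adjusted over the list alone), led by the transcription factor Batf3 at 2.44 ± 0.22. The dendritic cell mean was higher by 0.91, above every naive mouse in 7 of 8 mice (adjusted p = 0.00153, exact permutation test; adjusted p = 0.143 with an estimated correlation). Of 9 natural killer cell markers 7 rose (7 adjusted over the list alone), among them Il2rb by 1.42 ± 0.14 and Eomes by 1.16 ± 0.16. The natural killer cell mean was higher by 0.79, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.318 with an estimated correlation). Of 16 immediate early genes 9 rose (9 adjusted over the list alone), such as the transcription factors Myc by 1.89 ± 0.21 and Atf3 by 1.57 ± 0.25. The immediate early mean was higher by 0.47, above every naive mouse in 7 of 8 mice (adjusted p = 0.0144, exact permutation test; adjusted p = 0.503 with an estimated correlation). Without the arrays with high squamous epithelium scores this list was not called (adjusted p = 0.067, exact permutation test).

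Lower genes at 6 h were led by Krtap17-1 at -2.41 ± 0.27, 9330159F19Rik at -2.05 ± 0.25, the endothelial proteoglycan Esm1 at -1.99 ± 0.31, the scavenger receptor Scara5 at -1.97 ± 0.33 and Tmem35a at -1.84 ± 0.19. Of 12 alveolar type I cell markers 11 fell (11 adjusted over the list alone), with a mean of -0.24, below every naive mouse in 5 of 8 mice (adjusted p = 0.0082, exact permutation test; adjusted p = 0.467 with an estimated correlation). Of 14 endothelial cell markers 11 fell and 1 rose, and the same numbers adjusted over the list alone, with a mean of -0.23, below every naive mouse in 6 of 8 mice (adjusted p = 0.0074, exact permutation test; adjusted p = 0.511 with an estimated correlation). In limma 7540 genes passed the threshold, 3207 higher and 4333 lower. The log2 difference between the 3′ and 5′ actin probe sets, a measure of RNA integrity, differed by -0.18 in sensitized mice at 6 h (adjusted p = 0.0224, exact permutation test). This stood beside the higher and lower gene groups named at this time.

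**Figure D2:**
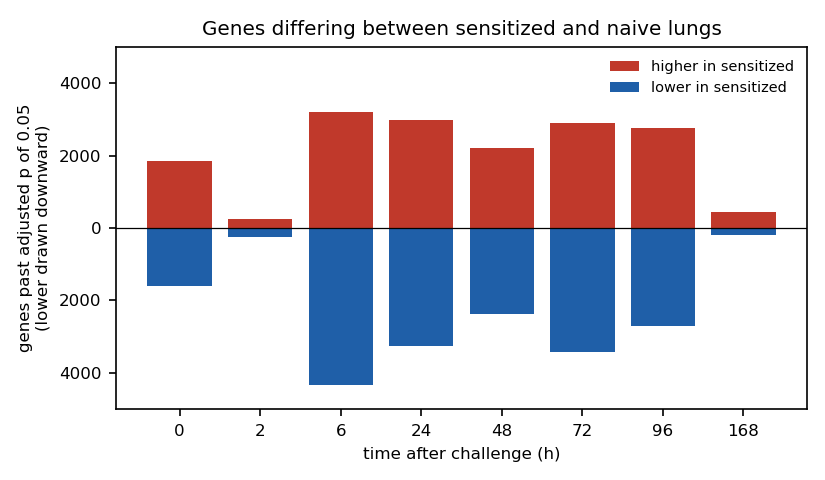
Number of genes past an adjusted p of 0.05 (y axis) that were higher (red, upwards) or lower (blue, downwards) in sensitized than in naive mice at each time after challenge in h (x axis). The counts ran from 491 at 2 h to 7540 at 6 h and came to 628 at 168 h.

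At 24 h chemokine, macrophage and mucus genes were higher in sensitized mice. Clca1 was higher by 8.65 ± 0.62 (SE; 6 sensitized and 8 naive mice), Chil4 by 6.63 ± 0.71, the ion transport regulator Fxyd4 by 5.83 ± 0.50 and Slc26a4 by 5.40 ± 0.51. Cd209e was higher by 4.98 ± 0.48, Ccl8 by 4.84 ± 0.40, Cxcl3 by 4.80 ± 0.58 and Scin by 4.63 ± 0.39. All 16 goblet cell and mucus genes rose, 16 adjusted over the list alone. The goblet cell mean was higher by 3.35, above every naive mouse in 6 of 6 (adjusted p = 0.00117, exact permutation test; adjusted p = 0.0298 with an estimated correlation). Of 9 CC chemokines of allergic inflammation 8 rose (8 adjusted over the list alone), with a mean higher by 2.57, above every naive mouse in 6 of 6 (adjusted p = 0.00117, exact permutation test; adjusted p = 0.123 with an estimated correlation). All 10 IL-4 and IL-13 responsive macrophage genes rose, 10 adjusted over the list alone, with the checkpoint ligand Pdcd1lg2 at 3.12 ± 0.34, the oxysterol-producing enzyme Ch25h at 2.99 ± 0.40 and the lipoxygenase Alox15 at 2.68 ± 0.60. The responsive macrophage mean was higher by 2.32, above every naive mouse in 6 of 6 (adjusted p = 0.00117, exact permutation test; adjusted p = 0.123 with an estimated correlation). Of 11 mast cell and basophil markers 7 rose and 1 fell, and the same numbers adjusted over the list alone, led by the mast cell proteases Mcpt2 at 3.63 ± 0.40 and Mcpt1 at 3.52 ± 0.35. The mast cell and basophil mean was higher by 0.96, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.359 with an estimated correlation). The basophil protease Mcpt8 was higher by 2.95 ± 0.33 at 6 h. Of 15 monocyte and tissue macrophage markers 11 rose and 1 fell at 24 h (12 and 1 adjusted over the list alone), among them Ms4a7 by 1.81 ± 0.25, Trem2 by 1.71 ± 0.22 and the complement gene C1qc by 1.53 ± 0.18. The monocyte and macrophage mean was higher by 0.87, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.239 with an estimated correlation).

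Of 21 extracellular matrix and remodelling genes 12 rose and 2 fell at 24 h (13 and 2 adjusted over the list alone), with the macrophage elastase Mmp12 at 3.67 ± 0.43, Timp1 at 3.04 ± 0.36 and the collagenase Mmp13 at 2.70 ± 0.49. The matrix list mean was higher by 0.64, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.503 with an estimated correlation). Of 10 club cell markers 6 fell and 2 rose, and the same numbers adjusted over the list alone, with Scgb3a2 at -0.91 ± 0.11 and the glutathione transferase Gsta3 at -0.87 ± 0.16, but Scgb3a1 at 0.92 ± 0.40. The club cell mean was -0.17, below every naive mouse in 0 of 6 mice (adjusted p = 0.0489, exact permutation test; adjusted p = 0.56 with an estimated correlation). The lowest gene was the fatty acid binding protein Fabp1, at 6.97 ± 0.30 (SD, n = 6) in sensitized and 11.08 ± 0.25 (SD, n = 8) in naive mice. It was followed by the HDL-associated esterase Pon1 at -2.72 ± 0.29, Vstm2a at -2.39 ± 0.29, Krtap17-1 at -2.38 ± 0.29 and Scara5 at -2.14 ± 0.35. In limma 6230 genes passed, 2982 higher and 3248 lower, with 428 and 82 at least 2-fold. The actin 3′ minus 5′ value differed by -0.13 at 24 h (adjusted p = 0.0224, exact permutation test), alongside these gene groups. Naive replicate 8 at 24 h had a high squamous epithelium score, 12.62, and without arrays of that kind the club cell list was not called (adjusted p = 0.0803, exact permutation test).

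At 48 and 72 h, with 8 sensitized mice at each time and 7 and 8 naive mice, genes of mucus, plasma cells and cell division were higher. At 48 h Clca1 was higher by 8.24 ± 0.60 (SE), Chil4 by 7.34 ± 0.68, Slc26a4 by 5.25 ± 0.49 and Scin by 5.24 ± 0.38. Cxcl3 was higher by 5.02 ± 0.55, Gcnt3 by 4.97 ± 0.30, Capn9 by 4.60 ± 0.35 and Fxyd4 by 4.53 ± 0.48. At 72 h the leading genes were Clca1 at 8.56 ± 0.58, Chil4 at 7.33 ± 0.66, Slc26a4 at 5.04 ± 0.47, Cxcl3 at 5.0 ± 0.54 and Gcnt3 at 4.96 ± 0.29. They were followed by Fxyd4 at 4.56 ± 0.46, Ccl8 at 4.54 ± 0.37 and AA467197 at 4.51 ± 0.44. All 16 goblet cell and mucus genes rose at both times, 16 adjusted over the list alone, with means higher by 3.38 and 3.31, above every naive mouse in 8 of 8 mice. Both differences passed (adjusted p = 0.00099, exact permutation tests; adjusted p = 0.00332 and 0.0211 with an estimated correlation). Of 13 plasma cell genes 10 rose and 1 fell at 48 h (11 and 1 adjusted over the list alone), with a mean higher by 1.08, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.123 with an estimated correlation). At 72 h 11 rose and 1 fell (12 and 1 adjusted over the list alone). Ighm stood at 4.04 ± 0.50, the plasma cell chaperone Mzb1 at 3.37 ± 0.26, Derl3 at 3.08 ± 0.21 and the immunoglobulin joining chain Jchain at 2.63 ± 0.26. The plasma cell mean was higher by 1.61, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.0191 with an estimated correlation). All 22 cell cycle genes rose at 48 and at 72 h, 22 adjusted over the list alone, among them Hmmr at 2.38 ± 0.24, Cdca8 at 2.06 ± 0.20 and Ube2c at 2.04 ± 0.18 at 72 h. The cell cycle mean was higher by 1.21 at 48 h and 1.48 at 72 h, above every naive mouse in 8 of 8 at both (adjusted p = 0.00099, exact permutation tests; adjusted p = 0.107 with an estimated correlation).

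Of 5 eosinophil markers 3 rose and 1 fell at 72 h, and the same numbers adjusted over the list alone. The eotaxin receptor Ccr3 stood at 2.50 ± 0.39, the major basic protein gene Prg2 at 2.15 ± 0.28, eosinophil peroxidase, Epx, at 1.16 ± 0.19 and Adgre4 at -0.54 ± 0.18. The eosinophil mean was higher by 1.07 (adjusted p = 0.00414, exact permutation test), above every naive mouse in 7 of 8 (adjusted p = 0.411 with an estimated correlation). At 48 h it was higher by 0.43, above every naive mouse in 6 of 8 and below every naive mouse in 1, and was not called (adjusted p = 0.141, exact permutation test). Of 14 unfolded protein response genes 10 rose at 72 h (10 adjusted over the list alone), led by Sdf2l1 at 1.56 ± 0.17 and Pdia4 at 1.40 ± 0.12. The unfolded protein response mean was higher by 0.59, above every naive mouse in 8 of 8 mice (adjusted p = 0.00099, exact permutation test; adjusted p = 0.193 with an estimated correlation). All 7 MHC class II presentation genes rose, 7 adjusted over the list alone, led by their transactivator Ciita at 0.89 ± 0.12. The MHC class II mean was higher by 0.56, above every naive mouse in 8 of 8 mice (adjusted p = 0.00099, exact permutation test; adjusted p = 0.181 with an estimated correlation). Of 14 endothelial cell markers 10 fell and 1 rose at 72 h (12 and 1 adjusted over the list alone), with Emcn at -0.60 ± 0.13 and the VEGF receptors Flt1 at -0.59 ± 0.09 and Kdr at -0.52 ± 0.08. The endothelial mean was -0.28, below every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.318 with an estimated correlation). Fabp1 was lowest at both times, at -2.69 ± 0.35 and -2.55 ± 0.34, ahead of Pon1 at -2.39 ± 0.27 and -2.48 ± 0.27. In limma 4579 genes passed at 48 h, 2216 higher and 2363 lower, with 285 and 11 at least 2-fold. At 72 h 6335 passed, 2901 higher and 3434 lower, with 347 and 32 at least 2-fold.

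At 96 h, with 8 sensitized and 7 naive mice, mucus and plasma cell genes were among those that differed most. Clca1 was higher by 8.55 ± 0.60 (SE), Chil4 by 7.18 ± 0.68, Scin by 4.71 ± 0.38, Slc26a4 by 4.54 ± 0.49 and Gcnt3 by 4.51 ± 0.30. Ighm was higher by 4.37 ± 0.52, Ccl8 by 4.31 ± 0.38, AA467197 by 4.28 ± 0.45, Mzb1 by 3.39 ± 0.27 and Jchain by 3.02 ± 0.26. Of 13 plasma cell genes 11 rose and 1 fell, and the same numbers adjusted over the list alone, with a mean higher by 1.59, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.0155 with an estimated correlation). All 16 goblet cell and mucus genes rose, 16 adjusted over the list alone, with a mean higher by 3.12, above every naive mouse in 8 of 8 mice (adjusted p = 0.00099, exact permutation test; adjusted p = 0.0191 with an estimated correlation). Of 14 ciliated cell genes 9 rose (11 adjusted over the list alone), with the regulator of motile cilia Foxj1 at 1.03 ± 0.16 and Rsph1 at 0.96 ± 0.13. The ciliated cell mean was higher by 0.41, above every naive mouse in 5 of 8 (adjusted p = 0.0235, exact permutation test; adjusted p = 0.451 with an estimated correlation). Of 12 alveolar type I cell markers 10 fell (10 adjusted over the list alone), with Sema3e at -0.50 ± 0.09, Vegfa at -0.37 ± 0.07 and the water channel Aqp5 at -0.36 ± 0.07. The alveolar type I mean was -0.26, below every naive mouse in 8 of 8 (adjusted p = 0.00117, exact permutation test; adjusted p = 0.181 with an estimated correlation). Fabp1 at -2.75 ± 0.35 and Pon1 at -2.07 ± 0.27 were the lowest genes. In limma 5483 genes passed, 2766 higher and 2717 lower, with 239 and 17 at least 2-fold.

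At 168 h fewer genes differed, while mucus and antibody genes were still high. Clca1 was higher by 7.77 ± 0.58 (SE; 8 and 8 mice), Chil4 by 5.58 ± 0.66, Ighm by 3.53 ± 0.50, Gcnt3 by 3.14 ± 0.29 and Slc26a4 by 3.03 ± 0.47. Cd209e was higher by 3.01 ± 0.44, Scin by 2.96 ± 0.36 and the kappa chain segment Igkv15-103 by 2.47 ± 0.50. Of 16 goblet cell and mucus genes 15 rose (15 adjusted over the list alone), with a mean higher by 1.92, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.00563 with an estimated correlation). Of 13 plasma cell genes 8 rose (10 adjusted over the list alone), with a mean higher by 1.07, above every naive mouse in 8 of 8 (adjusted p = 0.00099, exact permutation test; adjusted p = 0.00332 with an estimated correlation). Of 11 type 2 cytokines and receptors 1 rose adjusted over the list alone, and none over all genes in limma. The type 2 mean was higher by 0.27, above every naive mouse in 6 of 8 mice (adjusted p = 0.002, exact permutation test; adjusted p = 0.579 with an estimated correlation). Of 16 immediate early genes 5 fell (10 adjusted over the list alone), with the nuclear receptor Nr4a1 at -1.08 ± 0.26. The immediate early mean was -0.39, below every naive mouse in 6 of 8 (adjusted p = 0.00693, exact permutation test; adjusted p = 0.136 with an estimated correlation). Other low genes were Apold1 at -1.16 ± 0.19, Pon1 at -0.95 ± 0.27 and the gelatinase Mmp9 at -0.90 ± 0.24.

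In limma 628 genes passed at 168 h, 444 higher and 184 lower. The count was 364 without naive replicate 1, 409 without sensitized replicate 1, 362 with only the 2 groups fitted and 1570 with array weights. The actin 3′ minus 5′ value was higher in sensitized mice at 168 h, by 0.29 (adjusted p = 0.0319, exact permutation test), alongside the mucus, plasma cell and immediate early genes.

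**Figure D3:**
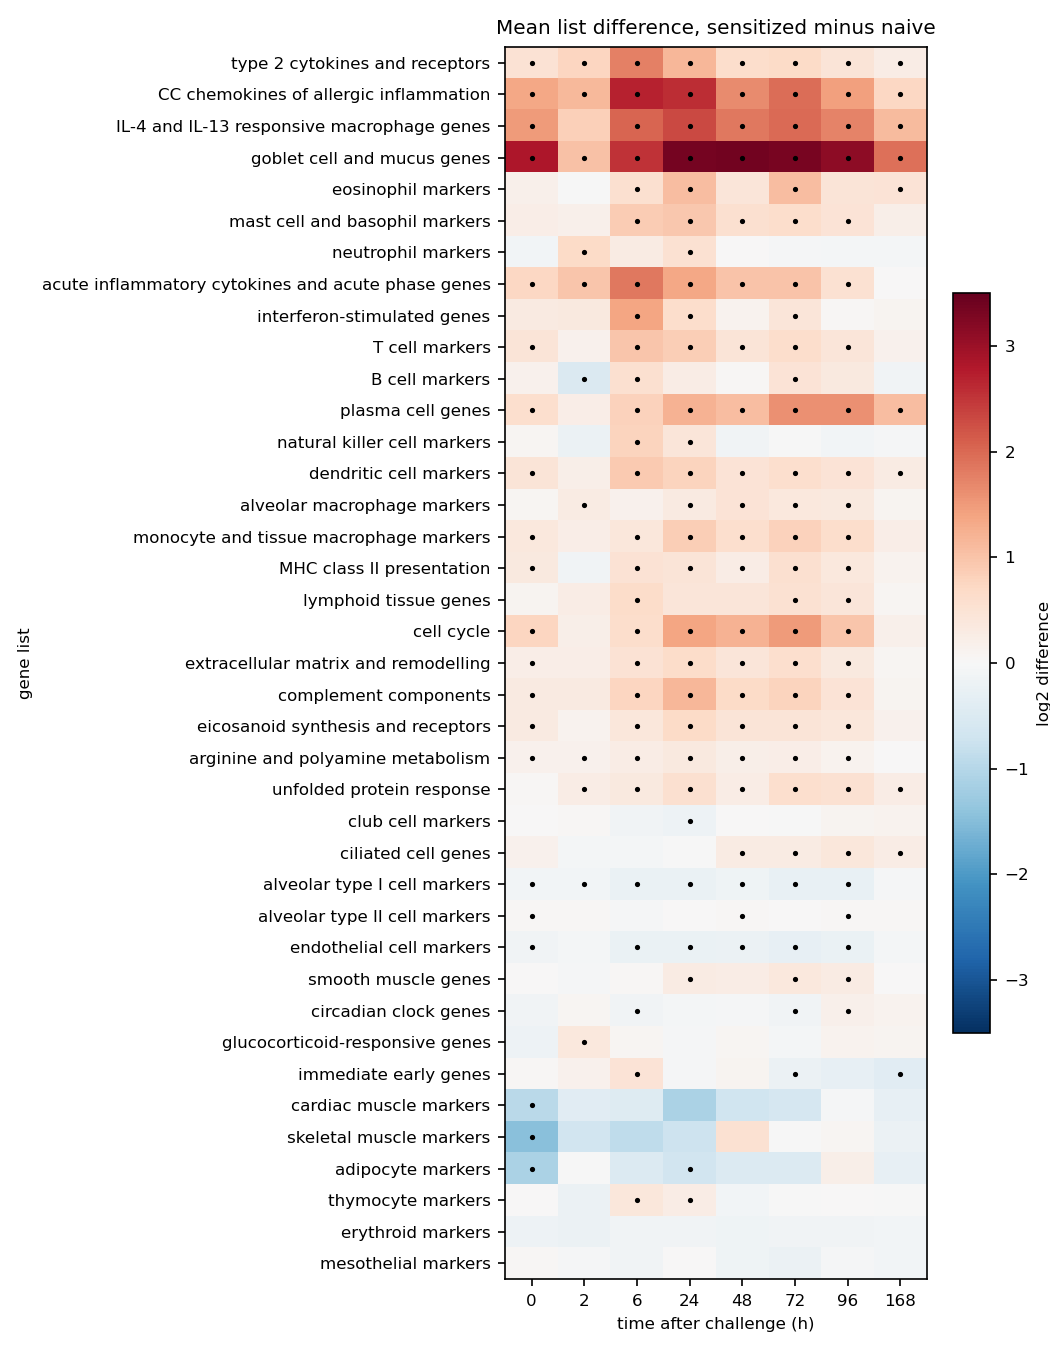
Difference of the mean log2 expression of 39 gene lists between sensitized and naive mice (colour, red higher and blue lower in sensitized mice) at each time after challenge in h (columns); dots mark an adjusted p under 0.05 in the exact permutation test. Of the 312 differences 172 were called, 149 higher and 23 lower, and 11 were called by camera with an estimated correlation.

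The change of the difference between the arms since 0 h was tested at each later time, in separate mice. At 2 h these mucus genes differed less than at 0 h: the difference fell by 3.36 for Clca1, 3.54 for Gcnt3 and 2.44 for Muc5ac. It rose by 1.89 for Il4 and 1.53 for Fkbp5. These changes average over a divided group. Sensitized 2 h replicates 2, 4 and 6 had goblet cell means of 7.99, 8.12 and 7.74, below the highest naive 2 h value of 8.26. Replicate 7 stood at 8.46. Il4 divided the group differently: it stood at 9.94 in replicate 4, but at 6.23, 5.96 and 6.28 in replicates 2, 6 and 7. No count was made with all of these mice left out. At 6 h the difference had risen by 4.36 for Cxcl11, 3.79 for Aldh1a3, 3.49 for Il6 and 3.38 for Il4. It had risen by 3.07 for Cxcl9, 2.84 for Mcpt8, 2.48 for Cxcl5 and 2.37 for the aggrecanase Adamts4, and fell by 2.68 for Gcnt3. At 24 h it had risen by 2.48 for Fxyd4, and fell by 3.09 for Fabp1. In limma 873 genes passed at 2 h (306 up, 567 down), 3210 at 6 h (1308 up, 1902 down) and 717 at 24 h (442 up, 275 down). A further 332 passed at 72 h (193 up, 139 down), 407 at 96 h (175 up, 232 down) and 253 at 168 h (126 up, 127 down). At 48 h limma called 0 genes, with 1438 at an unadjusted p under 0.05, 1299 with array weights, 1 with the mean of the probe sets of a gene and 0 under the other settings. These 7 contrasts share the 0 h mice.

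With each array centred on its median the split was 374 up and 353 down at 24 h and 160 up and 367 down at 96 h. With array weights 2825 genes passed at 2 h, 6930 at 6 h, 4262 at 24 h, 3180 at 72 h and 2122 at 96 h. Without the arrays with high squamous epithelium scores the split was 277 up and 239 down at 96 h and 290 up and 163 down at 168 h, and without those with high skeletal muscle scores as well 300 up and 262 down and 325 up and 194 down. With array weights the split was 1914 up and 2348 down at 24 h and 1378 up and 1802 down at 72 h. With the actin 3′ minus 5′ value as a covariate 2091 genes passed at 6 h, 337 at 24 h and 679 at 96 h (349 up, 330 down). With only the groups compared in the fit 2025 genes passed at 6 h, 1274 at 24 h and 22 at 168 h. The count at 6 h was 1634 without the arrays with high squamous epithelium scores and 2932 without those with high skeletal muscle scores as well. That at 168 h was 453 without these arrays, 519 without those with high skeletal muscle scores as well, 453 with array weights and 117 without naive replicate 4. The F test of limma for the interaction called 8164 genes. Of these, 1428 had their largest difference upwards and 2075 downwards at 6 h, against 926 and 575 at 24 h. Between 0 and 72 h, which had separate mice, 1527 genes were higher at both times, with 411 expected for independent lists, and 1272 were lower at both, with 423 expected. For 0 and 2 h, 88 genes were higher at both, with 34 expected, and 31 were lower at both, with 30.9 expected. The differences were correlated across genes for 28 pairs of times. Across the 13053 genes, which are not independent replicates, the differences at 0 h correlated with a Spearman's rho of 0.79 with those at 72 h, 0.764 with 24 h and 0.283 with 2 h.

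In naive mice, too, expression differed between times, and genes of the circadian clock were among those with the widest range. The clock output gene Dbp spanned 4.25 between time means, from 12.83 ± 0.17 (SD, n = 8) at 6 h to 8.58 ± 0.17 (SD, n = 7) at 96 h. The clock activators Npas2 and Arntl spanned 3.94 and 2.87 in the opposite order, Arntl from 7.92 ± 0.56 (SD, n = 8) at 6 h to 10.79 ± 0.16 (SD, n = 7) at 96 h. Per2 spanned 2.67, Per3 2.39 and Nr1d1 2.17. Beside these, Sphk2 spanned 3.38, Cxcl5 2.82, the cornified envelope gene Lor 2.6 and the heat shock gene Hspa1a 2.23. For Sphk2 this comes from the probe set used, and the difference between the arms reversed at 6 and 72 h outside it. Lor had an SD of 3.15 at 0 h, where 2 naive arrays had high squamous epithelium scores. The circadian list mean went from 10.86 at 6 h to 10.08 at 96 h and the glucocorticoid-responsive list mean from 12.17 to 11.67. Both had a permutation p = 1e-05, the smallest the resamples can give (adjusted p = 0.000195 over 39 lists). The unfolded protein response and alveolar type II lists passed as well (adjusted p = 0.0262 for both, permutation test). So did the CC chemokines, acute inflammatory genes and dendritic cells (adjusted p = 0.0421 for each, permutation test) and B cells (adjusted p = 0.0438, permutation test). Without naive 168 h replicate 4 the acute inflammatory list was not called (adjusted p = 0.111, permutation test), nor was the alveolar type II list without the arrays with high squamous epithelium scores (adjusted p = 0.058, permutation test). The actin 3′ minus 5′ value also differed between naive times, from 1.40 ± 0.08 (SD, n = 8) at 0 h to 1.09 ± 0.05 (SD, n = 7) at 48 h (permutation p = 1e-05, the smallest the resamples can give). Among 24, 48, 72 and 96 h, where its means lay between 1.09 and 1.11 (permutation p = 0.96), the circadian list passed (adjusted p = 0.00039, permutation test) and the other lists named here were not called (adjusted p from 0.094 to 0.693, permutation test). By the F test of limma 5015 genes differed between times in naive mice, 9218 with array weights, 4741 with the actin 3′ minus 5′ value as a covariate, and 11459 in sensitized mice. The counts of the 2 arms were not tested against each other.

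**Figure D4:**
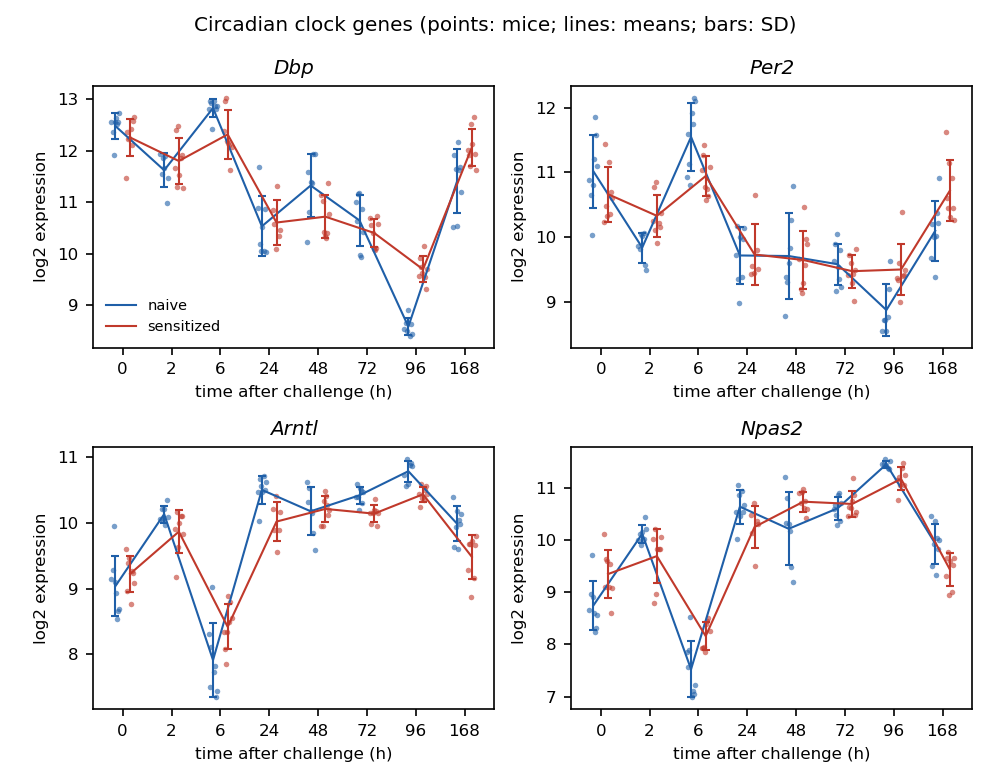
Log2 expression (y axis) of the clock genes Dbp, Per2, Arntl and Npas2 in each naive (blue) and sensitized (red) mouse against the time after challenge in h (x axis, evenly spaced categories); lines join group means and bars are SD. Dbp was highest and Arntl lowest at 6 h in naive mice, and at 96 h the order was reversed.

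The arms also differed in the clock genes at single times. At 96 h Dbp was higher in sensitized mice by 1.11 ± 0.21 (SE), Bhlhe40 by 0.69 ± 0.13, Per2 by 0.63 ± 0.22 and Nr1d1 by 0.41 ± 0.16. Of 17 clock genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), with a mean higher by 0.19, above every naive mouse in 4 of 8 mice (adjusted p = 0.0171, exact permutation test; adjusted p = 0.587 with an estimated correlation). At 6 h 4 rose and 10 fell, and the same numbers adjusted over the list alone, with a mean of -0.13, below every naive mouse in 5 of 8 mice (adjusted p = 0.0114, exact permutation test; adjusted p = 0.72 with an estimated correlation).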

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

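The redrawn labels and the tests of the 3 patterns weighed here were chosen after the results had been seen.

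The difference between the arms changed between times by the test of the interaction itself. In limma 8164 genes differed over all times. Against 0 h the difference changed for 873 genes at 2 h, 3210 at 6 h, 717 at 24 h, 332 at 72 h, 407 at 96 h and 253 at 168 h.

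Labels were redrawn 100 times, the real labels included, to ask whether chance could give as many genes. For the comparison of the arms, 1 of 100 splits, the real one, reached the real count at 0, 2, 6, 24, 48, 72 and 96 h. The highest other counts were 1481, 342, 6014, 4050, 2697, 3013 and 2589, against 3457, 491, 7540, 6230, 4579, 6335 and 5483. At 168 h 2 of 100 splits reached 628, and the other, which exchanged naive replicate 4 and sensitized replicate 6, gave 838. For the change since 0 h, 1 of 100 splits reached the count at 2 h (highest other 2), 24 h (highest other 0) and 168 h (highest other 10). It was 3 of 100 at 6 h (highest other 4467), 3 at 72 h (highest other 1684) and 2 at 96 h (highest other 992). For the comparison of the arms at each time, a share under 0.05 argues against chance. For the changes since 0 h, the redrawn labels also remove the difference at 0 h. These splits therefore cannot test whether that difference stayed unchanged, and chance is not excluded for those counts. Labels at 0 h and at the later time were redrawn separately. A split can therefore call more genes than the real labels, as at 6, 72 and 96 h. Which labels those splits kept was not examined. At 48 h the real count was 0, which 100 of 100 splits reach whatever the data (highest other 1), so the splits say nothing about it. The interaction F test (highest other 3862) and the time courses in naive (478) and sensitized mice (2932) were each reached by 1 of 100 splits. For the interaction F test the same limit holds as for the changes since 0 h.

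In each group of mice the mean of each list was searched for a mouse set apart from the others. For independent scores chance sets apart about 1 in 20 groups, or 32 of the 640 examined, and 66 were found, 41 in naive and 25 in sensitized groups. The 640 include the squamous epithelium list chosen after the data were seen, and the lists share mice, so 32 is only a rough guide. Naive 168 h replicate 4 stood apart in 12 lists. It was low in mast cell and basophil markers (7.19), club cells (12.4), ciliated cells (9.15), alveolar type I cells (12.58), endothelium (12.09) and cardiac muscle (9.01). It was high in alveolar macrophages (10.42), monocytes and macrophages (11.77), matrix genes (12.47), complement (10.66), arginine metabolism (10.48) and alveolar type II cells (13.81).

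Naive 24 h replicate 8 was high in IL-4 and IL-13 responsive macrophage genes (9.69), plasma cell genes (10.69), alveolar macrophages (10.5), lymphoid tissue (10.68), skeletal muscle (12.24) and squamous epithelium (12.62). Naive 0 h replicate 3 was high in CC chemokines (9.36), acute inflammatory genes (9.54) and eicosanoid genes (9.23) and low in alveolar type I cells (12.85). Naive 48 h replicate 3 was high in mast cell (8.07), alveolar macrophage (10.31) and adipocyte markers (9.9). Naive 6 h replicate 1 was high in smooth muscle (11.53), glucocorticoid-responsive genes (12.39) and skeletal muscle (13.05). Naive 72 h replicate 3 was high in type 2 genes (8.15) and monocytes and macrophages (11.27). Single high values in naive mice were T cells in 96 h replicate 3 (8.67), lymphoid tissue in 6 h replicate 4 (9.74), matrix genes in 6 h replicate 6 (11.67), eicosanoid genes in 2 h replicate 5 (9.17), alveolar type II cells in 0 h replicate 7 (13.69) and skeletal muscle in 2 h replicate 2 (12.44). Single low values were goblet cells in 168 h replicate 8 (7.45), mast cells in 24 h replicate 5 (7.43), neutrophils in 96 h replicate 2 (8.96), MHC class II in 2 h replicate 6 (11.47) and endothelium in 48 h replicate 4 (12.48).

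Among sensitized mice, 6 h replicate 3 was low in plasma cell (10.36) and immediate early genes (10.74) and high in skeletal muscle (9.21). Replicate 6 at 2 h was high in skeletal muscle (8.31) and low in squamous epithelium (5.62), and 48 h replicate 8 was high in both lists (12.28 and 12.55). Replicate 5 at 72 h was low in plasma cell (11.46) and glucocorticoid-responsive genes (11.6), and 168 h replicate 4 was low in acute inflammatory (9.07) and smooth muscle genes (10.87). Replicate 5 at 96 h was low in thymocyte markers (7.71) and high in squamous epithelium (6.04). Single high values were squamous epithelium in 6 h replicate 7 (12.12), acute inflammatory genes in 96 h replicate 2 (9.91), cell cycle genes in 168 h replicate 5 (9.04), alveolar type II cells in 24 h replicate 3 (13.68) and endothelium in 96 h replicate 4 (12.43). The clock genes of 24 h replicate 4 (10.56), the glucocorticoid-responsive genes of 48 h replicate 5 (12.16) and 168 h replicate 1 (12.53), and the immediate early genes of 48 h replicate 4 (11.28) were high too. Single low values were club cells in 2 h replicate 3 (12.54), alveolar type I cells in 0 h replicate 6 (12.63) and smooth muscle in 48 h replicate 1 (10.86).

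The first pattern weighed is that mucus, type 2 and cell cycle genes were high in sensitized mice at 0 h. For the goblet cell score a few deviating mice are argued against, since 8 of 8 sensitized mice lay above every naive mouse. The lowest stood at 10.16 against a highest naive value of 8.21. The type 2 and cell cycle genes were not weighed in this test. Sensitized 0 h replicates 1 and 6 had Il13 values of 9.45 and 9.14, against 6.89 to 7.89 in the others. Leaving out either lowered the count of genes at 0 h, so deviating mice remain open for the size of that difference. An exchange with sensitized mice of 24, 48 or 72 h is argued against by the clock genes. In 7 of 8 sensitized 0 h mice they lay nearer to naive mice of 0 h, while 22 of 22 sensitized mice of the later times lay nearer to their own side. A state that all sensitized mice carried before the challenge and kept to 2 h is argued against too. At 2 h 1 of 8 sensitized mice reached 10.16, with a median of 8.47 (exact permutation p = 0.00093). These 8 include replicates 2, 6 and 7, whose sensitization is in doubt, and the test was not repeated without them. Of the others, replicates 1, 3, 4 and 5 stood below 10.16, at 9.65, 8.49, 8.12 and 9.46, and replicate 8 at 10.74. Unequal earlier exposure, what 0 h means relative to the challenge, labels of whole times exchanged in both arms, and a separate cohort remain open. So does an exchange with sensitized mice of other times, such as 168 h. None of these was tested.

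The second pattern is that sensitized replicates 2, 6 and 7 at 2 h and 3 at 6 h had Il4 levels no higher than the highest naive mouse of their time (6.23, 5.96, 6.28 and 6.07). An exchange of labels with a naive-labelled mouse like most sensitized mice of its time is argued against: over the 14 panel genes 0 of 7 naive mice at 2 h and 0 of 8 at 6 h lay nearer to the sensitized than to the other naive mice (root mean square log2 distance, smallest margins 1.18 and 2.15, SD of the margins 0.23 and 0.50), while 5 of 8 and 7 of 8 sensitized mice lay nearer to the sensitized mean. In these 4 mice 1, 0, 6 and 10 of the 16 goblet cell genes lay above every naive mouse of the time, while single naive mice left out in turn reached up to 10. Their Clca1 values were 8.80, 5.34, 8.89 and 6.89, of which 8.80 and 8.89 lay above every naive mouse of any time. An unsensitized mouse labelled as sensitized cannot be told apart from failed sensitization or a missed challenge.

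The third pattern is the difference of clock genes between times in naive mice. If the whole-day times were collected at 1 hour of the day, the clock list was predicted not to differ between them. It did differ between naive groups at 0, 24, 48, 72, 96 and 168 h (permutation p = 1e-05, the smallest the resamples can give). The difference was thus not confined to 2 and 6 h. This test reuses the list and mice that gave the pattern, and influences other than the hour were not tested. It therefore cannot decide whether the hours differed. Collection at different hours may account for the pattern. Over the 8 naive time means Arntl and Dbp ran opposite (Pearson r = -0.828, exact permutation p = 0.0152). Spearman's rho was -0.976 (exact permutation p = 0.0004). Without the 2 times farthest from the median r was -0.931. The pair was chosen after the results had been seen, so its correlation restates the opposite course described above and is no independent test. Arntl and Dbp were the only pair whose correlation over the time means was computed, and no biological explanation was tested.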

How the results depend on the processing

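Leaving out single mice or the arrays with high scores of another tissue, the actin covariate, the naive lists among 24 to 96 h, and every setting but the 40% filter for the changes since 0 h, were chosen after seeing the data. Of 451 gene and time pairs, 451 had the same direction and call with a trended and robust model, 448 with median centring, 445 with repeated quantile normalization, 442 with the mean of probe sets, 418 with array weights, 429 with the actin 3′ minus 5′ value as a covariate (16 weaker, 6 stronger) and 399 with only the groups compared (29 weaker, 23 stronger). In other probe sets of the same genes 176 were the same, 22 weaker, 1 stronger and 9 reversed. No paired analysis was possible because replicate numbers follow the order of the deposited samples. The number of arrays, and compression of low signals by RMA, limit what can be seen.

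Testing each of the probe sets gave, with more features tested, 6157 calls at 0 h, 14032 at 6 h, 11905 at 24 h, 8529 at 48 h, 12046 at 72 h, 10053 at 96 h and 1052 at 168 h. Changes since 0 h then numbered 5259 at 6 h, 1215 at 24 h, 726 at 96 h and 429 at 168 h, with 10754 in the naive course, 22648 in the sensitized course and 15267 for the interaction. Without the 40% of genes with the lowest mean, fewer genes were tested, with 2286 calls at 0 h, 302 at 2 h, 4865 at 6 h, 2968 at 48 h, 4207 at 72 h and 308 at 168 h. Changes since 0 h were 551 at 2 h and 188 at 72 h, with 7239 in the sensitized course and 5343 for the interaction. Array weights gave 1379 calls at 2 h and 1570 at 168 h, changes since 0 h of 2825 at 2 h, 6930 at 6 h, 4262 at 24 h, 1299 at 48 h, 3180 at 72 h, 2122 at 96 h and 453 at 168 h, and 9218 in the naive course; the cause was not tested. With the mean of probe sets 1 gene changed at 48 h, and with only the groups compared 362 differed at 168 h, and changes since 0 h were 2025 at 6 h, 1274 at 24 h and 22 at 168 h; the cause was not tested. With the actin covariate changes since 0 h were 2091 at 6 h, 337 at 24 h and 679 at 96 h; the cause was not tested. Among 24, 48, 72 and 96 h, with fewer mice, 1 list differed between naive times, against 8. Which side held more genes changed with some settings for the arms at 0, 2, 24, 48, 72 and 96 h, and for the change since 0 h at 24, 72, 96 and 168 h.

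Without the arrays with high squamous epithelium scores, changes since 0 h were 1634 at 6 h and 453 at 168 h, and without those with high skeletal muscle scores as well 2932 at 6 h and 519 at 168 h; the cause was not tested. Leaving out 1 mouse gave 2003 to 4033 calls at 0 h, 197 to 577 at 2 h, 6820 to 8086 at 6 h, 5429 to 6287 at 24 h, 3984 to 4948 at 48 h and 364 to 776 at 168 h. Without naive 168 h replicate 4 the change to 168 h was 117 and the naive course 5037. Without sensitized 6 h replicate 3 the change to 6 h was 4408 and the interaction 8678. For lists, camera with an estimated correlation called 11 of 312, namely goblet cells at 0, 24, 48, 72, 96 and 168 h, plasma cells at 72, 96 and 168 h, and acute inflammatory genes and alveolar macrophages at 2 h. The other list settings called 158 to 172, against 172.

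Directions reversed with the median over members for dendritic cells at 72, 96 and 168 h (-0.026, -0.235 and -0.005), glucocorticoid-responsive genes at 72 h (0.302) and immediate early genes at 72 h (0.25), and with z scores for interferon-stimulated genes at 96 h (-0.27). They reversed in other probe sets of Aldh1a3 at 24, 48 and 72 h (-0.06, -0.029 and -0.073, and in another -0.1 and -0.021 at 48 and 72 h), Npas2 at 6 h (-0.002), Sphk2 at 6 and 72 h (0.013 and 0.244) and Synpo2 at 72 h (-0.126). The cause was not tested.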

Other observations

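The list tests here were set before the data were examined, and the values of single mice at the end were chosen after they had been seen. At 24 h, with 6 sensitized and 8 naive mice, 4 of 6 complement components rose (4 adjusted over the list alone), among them the regulator Cfi by 2.10 ± 0.22 (SE), the receptor C3ar1 by 1.85 ± 0.26 and Cfb by 1.30 ± 0.16. The complement mean was higher by 1.17, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.17 with an estimated correlation). Of 17 eicosanoid genes 12 rose (12 adjusted over the list alone), with the prostacyclin receptor Ptgir at 1.58 ± 0.16 and Alox12e at 1.55 ± 0.17. The eicosanoid mean was higher by 0.68, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.122 with an estimated correlation). Of 7 arginine and polyamine genes 3 rose (3 adjusted over the list alone), including the transporter Slc7a2 by 1.19 ± 0.14 and Arg2 by 0.92 ± 0.16. The arginine and polyamine mean was higher by 0.35, above every naive mouse in 6 of 6 mice (adjusted p = 0.00117, exact permutation test; adjusted p = 0.318 with an estimated correlation). At 6 h 3 of 6 lymphoid tissue genes rose (3 adjusted over the list alone), with lymphotoxin, Lta, at 1.38 ± 0.19 and the B cell attractant Cxcl13 at 1.15 ± 0.29. The lymphoid tissue mean was higher by 0.63, above every naive mouse in 4 of 8 mice (adjusted p = 0.00582, exact permutation test; adjusted p = 0.411 with an estimated correlation).

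At 72 h 7 of 11 smooth muscle genes rose and 1 fell, and the same numbers adjusted over the list alone, with the transcription coactivator Myocd at 0.94 ± 0.14 and the actins Actg2 at 0.83 ± 0.13 and Acta2 at 0.47 ± 0.06. The smooth muscle mean was higher by 0.38, above every naive mouse in 5 of 8 mice (adjusted p = 0.00448, exact permutation test; adjusted p = 0.398 with an estimated correlation). At 0 h 5 of 13 alveolar type II cell markers rose and 1 fell, and the same numbers adjusted over the list alone, with Chil1 at 0.42 ± 0.06 and the surfactant proteins Sftpd at 0.21 ± 0.04 and Sftpb at -0.18 ± 0.06. The type II cell mean was higher by 0.05, above every naive mouse in 3 of 8 mice (adjusted p = 0.00714, exact permutation test; adjusted p = 0.467 with an estimated correlation). Of 4 thymocyte markers 3 rose and 1 fell at 6 h, and the same numbers adjusted over the list alone, with Ccr9 at 0.90 ± 0.15 and Cd1d1 at -0.27 ± 0.10. The thymocyte mean was higher by 0.40, above every naive mouse in 5 of 8 mice (adjusted p = 0.00508, exact permutation test; adjusted p = 0.503 with an estimated correlation). The means of the 4 erythroid and 8 mesothelial markers were not called at any time in the exact permutation test. The erythroid mean was -0.20 at 2 h (adjusted p = 0.194, exact permutation test) and the mesothelial mean -0.21 at 72 h (adjusted p = 0.105, exact permutation test), where 4 mesothelial markers fell (4 adjusted over the list alone), such as Upk3b at -0.48 ± 0.11.

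At 2 h the Clca1 values of the 8 sensitized mice were 13.54, 8.80, 11.68, 7.47, 13.38, 5.34, 8.89 and 14.09. At 168 h sensitized replicate 6 had a Clca1 value of 10.66, against a lowest of 12.92 in the other sensitized mice.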
